A study of Mus musculus with 12 samples.

How the data were processed

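RNA was measured by Illumina sequencing in γδ and CD4+ T cells sorted by flow cytometry into lysis buffer. Per the submitters' processing notes, reads were handled with bcl2fastq, STAR, featureCounts and DESeq2 on the mm10 (GRCm38) build, with no versions given. The authors deposited a table of raw counts per gene, and the deposited FPKM values were used only as an alternative. The table held 52459 genes in 12 libraries, in 6 groups of 2, taken from the labels. Gene positions came from GENCODE vM21.

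Total counts per library ranged from 17035638 to 23203603. Non-mitochondrial counts were 7977220 and 9000102 in the γδ libraries of the MCD diet and 9559392 to 10851934 in the other 10. The number of genes with at least 10 counts was 8989 and 10125 in the γδ MCD libraries, 11903 and 12174 in the γδ control libraries and 12100 to 13402 in CD4+ libraries. Pearson's r of log2 CPM between the 2 replicates, across genes, which are not independent replicates, was 0.732 in γδ MCD, 0.807 in γδ control and 0.84 to 0.863 in CD4+ groups. A floor of 3 counts corresponded to 0.13 to 0.248 CPM. Where a group was at 0, the fold was computed against 3 counts in each of its libraries and given as a lower bound; with 1 to 3 counts, an exact 95% interval of the ratio was given. Floors and intervals cover counting error only.

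Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16218. All 12 libraries were fitted together with 1 coefficient per group in edgeR 4.0.16 (TMM scaling, quasi-likelihood test, 2-sided) under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes used a prior count of 2, and averages gave each group equal weight. CPM values were scaled by TMM. Folds were ratios of mean CPM. The comparisons were the diets within each cell type and genotype, the genotypes within each diet, γδ against CD4+ T cells in wild-type mice, both averages over CD4+ T cells and both interactions.

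Gene lists of T cell programmes, signalling, metabolism and markers of other cells were written before the data were examined, as were the comparisons, the tests and the rule for naming genes. A pair of lists, ribosomal proteins and mitochondrial mRNA, was added later, and 49 lists were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over lists within a comparison. The test was repeated with an estimated correlation and with fry. A list's median was given a further time with each gene that was at 0 in a group set at the floor of 3 counts. The genes named per comparison were up to 8 higher and 8 lower genes with the largest log2 fold change among those past the threshold, without overlap between libraries and with a mean of at least 5 CPM in the higher group. Receptor and immunoglobulin segments, unnamed transcripts and pseudogenes were left out of this rule. Where fewer than 5 passed in a direction, the 5 smallest p-values among genes under the same CPM limit and exclusions were given as values, without the condition on overlap. Up to 4 members of each described list and the label genes were named too. Some genes that the rule names are not reported.

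Alternatives were RLE and library-size scaling, DESeq2 1.42.0, limma-voom, robust spread, log2 FPKM with pseudocounts of 1 and 0.1, no filter, a mean of at least 50 reads, only the groups compared, no receptor segments, thinning to equal totals, a replicate block in knockout libraries, and leaving out each library in turn. The test was also run on simulated data, with 50 genes changed at each size, raised and lowered in turn. Library sizes were real, but each gene had the same mean and spread in all groups before the change. The spread of each group was thus not modelled on its own. In these data 16-fold changes were recovered in 15 of 50 genes in γδ, 19 in wild-type CD4+ and 10 in knockout CD4+ T cells. At 4-fold 0, 3 and 3 were recovered, and 0, 3 and 3 of 16018 unchanged genes were called. A raised list was recovered in all 3 settings, and 0 of 20 unchanged lists were called in each. Genes were simulated independently, so this does not check the preset correlation.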

Results

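RNA sequencing was carried out on sorted T cells of mice in a study of steatohepatitis, a fatty liver disease with inflammation. γδ T cells carry a T cell receptor made of a γ and a δ chain, while CD4+ T cells carry an αβ receptor and the co-receptor CD4. Mice were 7 weeks old at the start and ate a control diet or a methionine- and choline-deficient (MCD) diet, which causes fat storage and inflammation in the mouse liver, for 6 weeks. The 12 libraries formed 6 groups of 2: γδ T cells of wild-type mice on either diet, CD4+ T cells of wild-type mice on either diet, and CD4+ T cells of mice lacking the γδ T cell receptor (knockout) on either diet. Total counts per library were 21539431 and 21759167 in knockout control, 18528243 and 18320601 in knockout MCD, 17988045 and 18410553 in wild-type control and 17035638 and 17093398 in wild-type MCD CD4+ T cells. The γδ T cells had 22930004 and 23203603 counts on the control diet and 18466126 and 19498448 on the MCD diet. The labels name no tissue and do not say that the replicates are separate mice, so every p-value measures only the spread between these samples.

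Trdc, the δ-chain constant gene, had 7552 to 14401 counts in the 4 γδ libraries. The labels do not state which gene the knockout removes, and Trdc was scarce in all CD4+ T cells: 66 and 165 counts in knockout control, 80 and 20 in knockout MCD, 18 and 62 in wild-type control and 57 and 5 in wild-type MCD libraries. These few reads in cells that do not use the δ chain do not check the genotype. Cd4 read 632 to 1448 CPM (counts-per-million) in the 8 CD4+ libraries and 0.975 to 4.29 CPM in the γδ libraries. Cd3e, a component shared by both receptors, read 621 to 1107 CPM in CD4+ and 976 to 1608 CPM in γδ libraries. The αβ constant gene Trac read 339 to 655 CPM in CD4+ and 30.1 to 87.2 CPM in γδ libraries, and Trbc2 read 151 to 372 CPM and 16.1 to 163 CPM. Cd8a read 0.0488 to 11.2 CPM in CD4+ and 51.7 to 322 CPM in γδ libraries. The Y-linked gene Ddx3y read 34.8 to 91.2 CPM in the 12 libraries, and Xist read 0 to 1.32 CPM. Mitochondrial genes took 40.8% to 52.7% of the counts in CD4+ and 53.8% to 56.8% in γδ libraries.

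The comparison of diets in γδ T cells of wild-type mice asked how their transcriptome differed on the MCD diet. Nfe2l2, which encodes the NRF2 regulator of antioxidant genes, read 1046 ± 105 CPM (SD, n = 2) on the MCD diet and 237 ± 82.8 CPM (SD, n = 2) on the control diet, a 4.42-fold difference. Its target Slc7a11, a cystine transporter, read 130 ± 14.2 CPM against 0.258 ± 0.211 CPM (SD, n = 2), and the superoxide dismutase Sod2 read 342 ± 64.9 CPM against 96.3 ± 28.3 CPM. The cytotoxic protease Gzmb read 145 ± 58.0 CPM on the MCD diet and 558 ± 133 CPM on the control diet (SD, n = 2). None of these genes passed the adjustment over all genes (adjusted p = 0.0724 to 0.223). The diets did not overlap, as is common by chance in groups this small.

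As a group, the oxidative stress (NRF2) list rose on the MCD diet in γδ T cells: 21 of 23 measured members were higher, among them Slc7a11, Sod2, Fth1 (2.45-fold) and Hmox1 (13.7-fold). Its median log2 fold change was 1, against -0.06 over all genes (camera adjusted p = 0.000489). None of the 10 lists called between diets in γδ T cells held with an estimated correlation (adjusted p = 0.082 to 0.455). The proliferation list fell, with 24 of 32 members lower and a median of -1.64, or -1.65 with genes at 0 in a group set at the floor of 3 counts (adjusted p = 0.000489). Cenpf was at least 67.1-fold lower and Rrm2 128-fold lower on the MCD diet. The sterol synthesis list fell (14 of 21 lower, median -1.56, -1.60 at the floor, adjusted p = 0.0125), with Dhcr7 91.8-fold lower. The NF-kB and inflammasome list rose (14 of 20 higher, median 0.92, adjusted p = 0.0125), with Birc3 3.18-fold and Traf1 3.85-fold higher. The immediate early list rose (18 of 20 higher, median 0.63, 0.64 at the floor, adjusted p = 0.0108), with Junb 5.07-fold and Atf3 22.8-fold higher. The type 17 list, of genes for interleukin-17 production, rose weakly (13 of 16 higher, median 0.34, 0.46 at the floor, adjusted p = 0.0369). Within it Il18r1 read 1024 ± 185 CPM against 548 ± 63.8 CPM (SD, n = 2). Il17a read 1.82 and 40.7 CPM on the MCD diet and 0.92 and 3.47 CPM on the control diet.

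Markers of other cells moved in γδ T cells beside these groups. The sinusoidal endothelium list was lower in all 16 members (median -5.79, -6.06 at the floor, adjusted p = 1.93e-10), with Kdr at least 185-fold, Oit3 at least 194-fold and Dnase1l3 14.7-fold lower. The B and plasma cell list fell (13 of 15 lower, median -2.33, -2.21 at the floor, adjusted p = 0.024), with Igkc 19.3-fold lower, as did the erythroid list (3 of 3 lower, median -4.01, -3.27 at the floor, adjusted p = 0.018). The neutrophil and monocyte list rose (13 of 15 higher, median 0.69, 0.70 at the floor, adjusted p = 0.000814), with Clec4e 22.6-fold higher. The type 1 and cytotoxic, regulatory, naive and central memory, TCR activation and checkpoint lists were not called between diets (adjusted p = 0.272 to 0.958).

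Between diets in γδ T cells, 0 of 16218 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (lowest adjusted p = 0.0548). At an unadjusted p under 0.05 there were 2839 genes, 1020 higher and 1819 lower on the MCD diet, against 811 given by chance. With only the γδ groups fitted there were 1187, so the size of this excess depended on which libraries shared the spread. DESeq2 called 2105 genes and limma-voom 63. Leaving out MCD replicate 2 gave 484 genes and leaving out MCD replicate 4 gave 1342. Where the mean was at least 5 CPM in the higher group, the smallest p-values among higher genes belonged to Kmt5a (425 ± 27.5 CPM against 87.7 ± 25.6 CPM), Xylt1 (8.82-fold), Plpp6 (20.7-fold), Nfe2l2 and Spsb1 (at least 50.3-fold). Among lower genes under the same limit they belonged to Trmt61a (0.225 ± 0.0326 CPM against 63.4 ± 39.5 CPM), Cep97 (22.4-fold) and Chst2 (0.199 CPM against 20.1 CPM), each with adjusted p between 0.0548 and 0.0724. Kif11 had 1 count on the MCD diet and a ratio of 325 (95% counting interval 58.1 to 12900), and Rae1 had 1 count and a ratio of 405 (72.4 to 16000). Adjusted over the list alone, 11 endothelial, 11 proliferation and 6 sterol members were lower and 3 oxidative stress members higher, beside 0 over all genes. The type 17 call was lost without control replicate 7 or either MCD replicate (adjusted p = 0.132 to 0.258), the immediate early call without control replicate 7 or MCD replicate 4 (0.104 to 0.206), and the NF-kB call without MCD replicate 4 (0.206). Without control replicate 6 or MCD replicate 4 the sterol call (0.0536 to 0.0675) and the erythroid call (0.169 to 0.206) were lost. The neutrophil call was lost without MCD replicate 4 (0.0536), and the B cell call without any 1 of the 4 γδ libraries (0.0675 to 0.254).

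**Figure D1:**
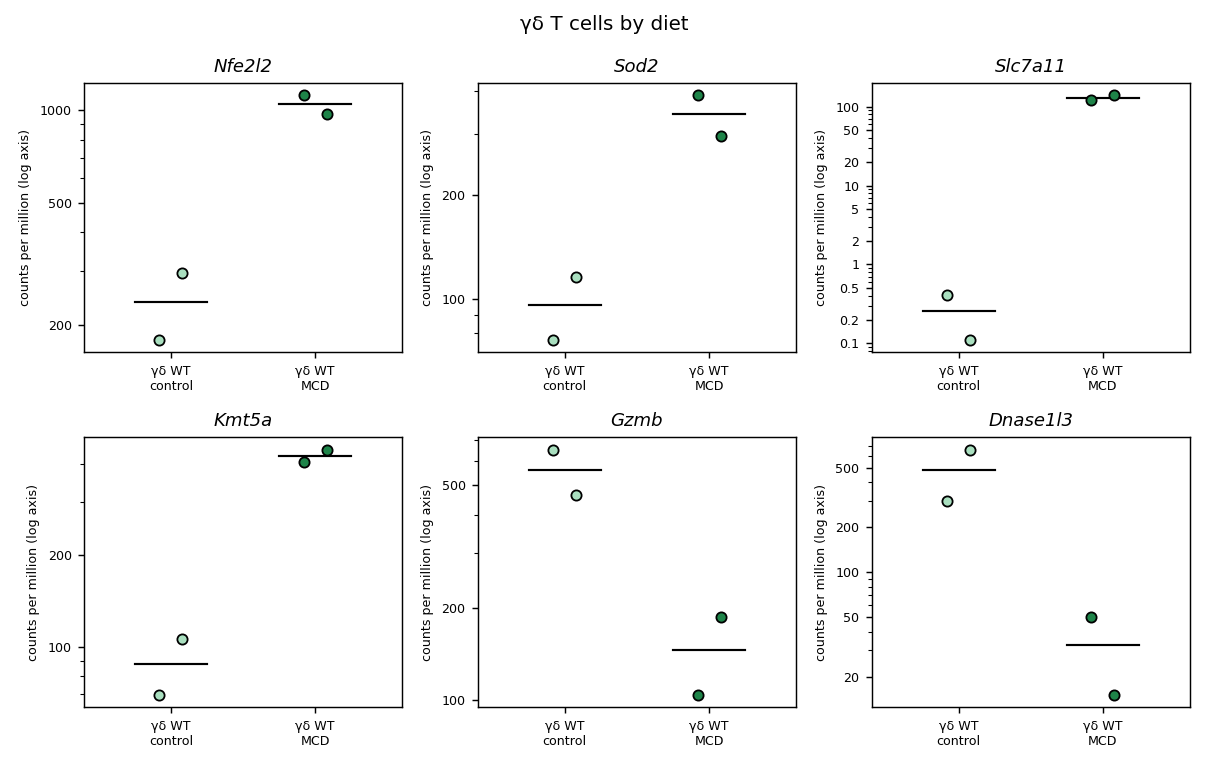
CPM on a log axis in γδ T cells of wild-type mice by diet, with 1 point per library and a line at the mean of 2. Nfe2l2 read 178 and 295 CPM on the control diet and 972 and 1120 CPM on the MCD diet, and Dnase1l3 read 299 and 661 CPM and then 15.2 and 50.3 CPM.

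The comparison of diets in wild-type CD4+ T cells asked how these cells differed on the MCD diet where γδ T cells were present. Ahnak, a large scaffold protein gene, read 1420 ± 92.9 CPM (SD, n = 2) on the MCD diet and 754 ± 98.4 CPM (SD, n = 2) on the control diet. The chemokine gene Ccl5 read 68.0 ± 1.01 CPM against 29.5 ± 2.71 CPM, and the interleukin-18 receptor gene Il18r1 read 240 ± 3.85 CPM against 134 ± 0.279 CPM (SD, n = 2). The signalling receptor gene Slamf7 read 26.5 ± 7.22 CPM against 140 ± 22.7 CPM, and the naive-cell regulator Satb1 was 1.54-fold lower, at 1102 ± 40.3 CPM on the control diet. Each gene had an adjusted p of 1. The diets did not overlap, as is common by chance in groups this small.

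As groups, wild-type CD4+ T cells showed a higher type 17 list on the MCD diet (14 of 16 members higher, median 0.89, 1.06 with genes at 0 set at the floor, adjusted p = 0.00432). Of the 6 lists called here, the hepatocyte list held with an estimated correlation (adjusted p = 0.0162) and the other 5 did not (0.119 to 0.312). The proliferation list fell (23 of 32 lower, median -0.69, -0.72 at the floor, adjusted p = 0.00913), with Rrm2 3.57-fold and Top2a 1.95-fold lower. Several lists of liver cell transcripts fell, while the 2 measured cholangiocyte genes went 1 each way (median 1.63, adjusted p = 0.0574, not called). The hepatocyte list was lower in 16 of 18 members (median -3.06, -2.5 at the floor, adjusted p = 6.55e-10), and albumin (Alb) read 0.364 ± 0.319 CPM on the MCD diet against 17.1 ± 5.93 CPM (SD, n = 2). The sinusoidal endothelium list fell (12 of 16 lower, median -2.12, -2.22 at the floor, adjusted p = 2.71e-07), with Ptprb 57.4-fold lower. The stellate and fibroblast list (7 of 9 lower, median -2.98, -4.24 at the floor, adjusted p = 0.000113) and the macrophage and Kupffer list (15 of 18 lower, median -0.66, -0.94 at the floor, adjusted p = 0.00432) also fell. In the latter, Lyz2 was 4.33-fold lower and Vsig4 at least 34.0-fold lower. The type 1 and cytotoxic, regulatory, naive, TCR activation and checkpoint lists were not called (adjusted p = 0.133 to 0.817), although Tigit read 76.1 ± 33.3 CPM against 19.4 ± 4.19 CPM.

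In wild-type CD4+ T cells, 0 of 16218 genes passed edgeR's test between diets, with 346 genes at an unadjusted p under 0.05, 153 higher and 193 lower, fewer than the 811 given by chance. Fitted with CD4+ libraries only, 731 genes had such a p, so this count depended on which libraries shared the spread. DESeq2 called 40 genes and limma-voom 0. Besides Ahnak, the smallest p-values among higher genes with a mean of at least 5 CPM in the higher group were those of Cdk6 (3.05-fold), Snx10 (8.77-fold), Dkk3 (at least 43.1-fold) and Rnd3, which had 2 counts on the control diet and a ratio of 210 (95% counting interval 57.8 to 1740). Among lower genes under the same limit they were those of Slamf7, Alb, Ptprb, Rgs5 (1 count on the MCD diet, ratio 276, interval 49.1 to 10900) and Csf3r, which was at 0 in 3 of the 4 libraries and at 20.03 CPM in control replicate 3. Without MCD replicate 3 the type 17 call was lost (adjusted p = 0.0748). The proliferation call was lost without control replicate 3 or MCD replicate 1 (0.221 to 0.247), and the macrophage call without control replicate 2 or MCD replicate 1 (0.177 to 0.221).

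The same comparison in knockout CD4+ T cells asked how the diet acted where γδ T cells were absent. Rgs1, a regulator of chemokine signalling (chromosome 1, 144242296 to 144249242 in GRCm38), rose 6.59-fold on the MCD diet, from 73.7 ± 4.56 to 486 ± 0.361 CPM (SD, n = 2; adjusted p = 0.00667). The transcription factor gene Maf (chromosome 8, 115682942 to 115707794) rose 6.58-fold, from 40.3 ± 5.05 to 265 ± 6.53 CPM (adjusted p = 0.0155). Ccl5 (chromosome 11, 83525778 to 83530518) rose 5.12-fold, from 28.7 ± 4.47 to 147 ± 26.4 CPM, and Ahnak (chromosome 19, 8989284 to 9076914) rose 2.65-fold, from 518 ± 69.7 to 1371 ± 176 CPM (both adjusted p = 0.0356). Il1rn, for the interleukin-1 receptor antagonist, rose from 1 count to 236 counts, a ratio of 224 (95% counting interval 39.9 to 8900; adjusted p = 0.0356). The mitochondrial ribosomal RNA mt-Rnr2 fell 1.5-fold (log2 fold change -0.59, SE 0.08, adjusted p = 0.0341). The diets did not overlap in these 6 genes, as the naming rule asked.

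Activation and effector groups rose together in knockout CD4+ T cells on the MCD diet at the preset correlation, and none of the 19 lists called in this comparison held with an estimated correlation (adjusted p = 0.0548 to 0.481). Mitochondrial genes took 52.7% and 51.1% of the counts in the knockout control libraries and 43.9% and 41.1% in the knockout MCD libraries, beside 40.8% to 43.9% in wild-type CD4+ T cells. The TCR activation list was higher in 20 of 22 members (median 1.33, 1.37 with genes at 0 set at the floor, adjusted p = 1.19e-06), with Bhlhe40 5.57-fold and Nr4a1 8.08-fold higher. The type 1 and cytotoxic list rose (19 of 24 higher, median 1.31, 1.32 at the floor, adjusted p = 2.05e-05), with Gzmk 78.9-fold and Ccl3 650-fold higher and Ccl4 at a ratio of 505 over 1 count (95% counting interval 90.2 to 20000). The type 17 list (14 of 16 higher, median 1.41, 1.42 at the floor, adjusted p = 4.41e-05) included Maf, Rora (2.73-fold) and Il21, which was at least 178-fold higher. Tissue residency (14 of 15 higher, median 0.99, 1 at the floor, adjusted p = 2.21e-05) included Rgs1, Itga1 (6.09-fold) and Prdm1 (7.07-fold). Chemokines (12 of 14 higher, median 2.35, 2.60 at the floor, adjusted p = 6.18e-05), follicular helper genes (11 of 11 higher, median 0.66, 0.67 at the floor, adjusted p = 0.000999) and regulatory genes (15 of 18 higher, median 1.06, 1.19 at the floor, adjusted p = 0.00522) rose as well. Pdcd1 was 31.2-fold, Il10 99.2-fold and Tnfrsf18 15.6-fold higher. The checkpoint list rose (11 of 14 higher, median 1.52, 1.15 at the floor, adjusted p = 0.0191), with Tigit 7.07-fold and Entpd1 5.36-fold higher. Cytokines (16 of 26 higher, median 0.81, 0.91 at the floor, adjusted p = 0.00866), NF-kB (17 of 20 higher, median 0.72, 0.81 at the floor, adjusted p = 0.00866; Casp1 5.25-fold) and NK receptor genes (11 of 15 higher, median 2.07, 2.12 at the floor, adjusted p = 0.00507; Klri2 at least 49.9-fold) also rose.

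Genes of resting T cells fell in the same knockout libraries. The naive and central memory list was lower in all 17 members (median -1.19, adjusted p = 1.89e-06), with Satb1 (572 ± 65.0 CPM against 1442 ± 70.2 CPM; SD, n = 2), Tcf7 (426 ± 66.9 CPM against 970 ± 163 CPM) and Foxp1 (2-fold lower). Ribosomal protein genes, a list added after the data were seen, were lower in 82 of 83 members (median -1.11, adjusted p = 4.92e-22), with Rpl4 2.20-fold lower. These genes held 2.22% and 2.62% of the non-mitochondrial counts in the knockout control libraries and 1.16% to 1.70% in the other CD4+ libraries. The oxidative phosphorylation list fell (36 of 54 lower, median -0.32, adjusted p = 0.0405; Atp5b 1.92-fold lower), as did hepatocyte transcripts (13 of 18 lower, median -1.59, -1.69 at the floor, adjusted p = 0.000834). The list for cholangiocytes had 2 measured members, both higher (median 5.03, 4.89 at the floor, adjusted p = 0.000846), 1 of which was Spp1, at least 238-fold higher. The apoptosis and p53 (15 of 21 higher, median 0.49, adjusted p = 0.0309; Tnfsf10 3.13-fold), immediate early (15 of 20 higher, median 0.47, 0.48 at the floor, adjusted p = 0.0405; Dusp1 2.77-fold) and type 2 lists (6 of 9 higher, median 1.15, 1.52 at the floor, adjusted p = 0.0483) rose.

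In knockout CD4+ T cells, 6 of 16218 genes passed edgeR's test between diets, 5 higher and 1 lower, and 982 had an unadjusted p under 0.05, against 811 given by chance. Among the 12 fits without 1 library, the call was kept in 9 for Rgs1, 8 for Maf and mt-Rnr2, 6 for Il1rn, 5 for Ahnak and 2 for Ccl5, with adjusted p up to 0.473. The log2 fold change of Il1rn, 5.46 over all libraries, was 6.22 without MCD replicate 1 and 3.68 without MCD replicate 2. Of 16 other settings, all kept the calls of Rgs1 and Maf, 15 that of Ccl5, 12 that of Ahnak and 9 that of Il1rn, and 9 of 15 kept that of mt-Rnr2. DESeq2 called 266 genes and limma-voom 19. Leaving out knockout control replicate 1 or 2, or knockout MCD replicate 2, gave 0 genes, and leaving out knockout MCD replicate 1 gave 2. Leaving out γδ MCD replicate 2 gave 41 and γδ MCD replicate 4 gave 42, since these libraries enter the shared spread. Below the threshold, mt-Rnr1 was 1.57-fold, Ssh2 2.32-fold, Satb1 2.52-fold and Add3 2.67-fold lower, each with adjusted p = 0.0909. Adjusted over the list alone, 6 type 1, 5 chemokine, 4 type 17 and 4 residency members were higher, beside 1 in each list over all genes, and 6 naive members were lower, beside 0. Without knockout control replicate 1 or MCD replicate 1 the regulatory (adjusted p = 0.079 to 0.152), checkpoint (0.134 to 0.326), cytokine (0.0728 to 0.151) and NK calls (0.052 to 0.294) were lost. Without control replicate 1 the follicular helper (0.079) and NF-kB calls (0.052) were lost. The type 2, immediate early, oxidative phosphorylation and apoptosis calls were each lost in 4 to 8 of the 12 fits without 1 library, at up to 0.311, 0.536, 0.272 and 0.117. The other 9 called lists kept their calls in all 12 fits.

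**Figure D2:**
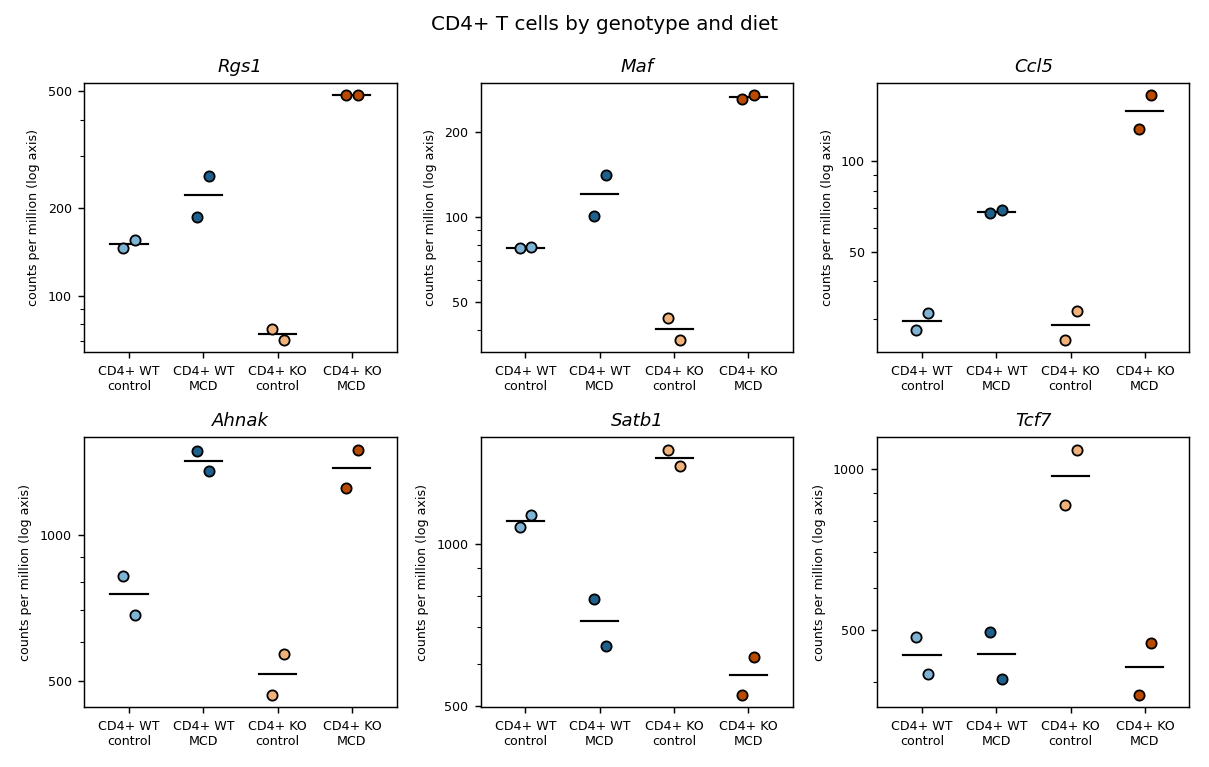
CPM on a log axis in CD4+ T cells by genotype and diet, with 1 point per library and a line at the mean of 2. Rgs1 read 70.5 and 76.9 CPM in knockout control and 485 and 486 CPM in knockout MCD libraries, beside 145 and 155 CPM and 186 and 257 CPM in wild type.

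Averaged over both genotypes with equal weight, the diet comparison asked what the MCD diet changed in the mean of the genotypes. A call here does not show a change in each genotype. The immunoreceptor gene Lilr4b rose 9.49-fold, from 13.3 ± 7.14 to 126 ± 61.9 CPM (SD, n = 4; adjusted p = 0.0479). Ccl5 rose 3.70-fold, from 29.1 ± 3.05 to 108 ± 48.2 CPM (adjusted p = 0.0161), and Maf rose 3.27-fold, from 59.1 ± 21.9 to 193 ± 85.1 CPM (adjusted p = 0.0186). Rgs1 rose 3.15-fold, from 112 ± 44.6 to 354 ± 155 CPM, and Ahnak rose 2.20-fold, from 636 ± 153 to 1396 ± 118 CPM (both adjusted p = 0.0156). Il1rn, named after its values were seen, had the log2 fold change 4.14 (SE 0.54, adjusted p = 0.0156), at 1.52 to 9.34 CPM on the MCD diet and 0 to 0.22 CPM on the control diet. In all 6 genes the 4 MCD libraries lay above the 4 control ones, but none was called for genotype by diet. Log2 fold changes in wild type and knockout were 0.56 and 2.72 for Rgs1, 0.63 and 2.72 for Maf, 1.2 and 2.35 for Ccl5, 0.91 and 1.41 for Ahnak, 2.06 and 4.5 for Lilr4b and 2.82 and 5.46 for Il1rn. None of the 6 was called in wild type alone (adjusted p = 1). Without knockout MCD replicate 2 the average for Il1rn was 3.25 and not called (adjusted p = 0.0504).

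These were all 6 genes called over the 8 CD4+ libraries, with 986 genes at an unadjusted p under 0.05 against 811 given by chance. Their calls were kept in 6 of the 12 fits without 1 library for Rgs1, Ahnak and Il1rn and in 5 for Ccl5, Maf and Lilr4b, with adjusted p up to 0.471. Spp1 was at least 127-fold higher and Gzmk 58.8-fold higher without passing (adjusted p = 0.0774 and 0.139), and Satb1 was 1.97-fold, Selenop 2.17-fold and Actb 1.52-fold lower (0.0774 to 0.171). Of 21 called lists, the hepatocyte list held with an estimated correlation (adjusted p = 0.0157) and the other 20 did not (0.0596 to 0.254). The type 17 list rose (15 of 16 higher, median 0.82, 1 at the floor, adjusted p = 2.28e-06), as did TCR activation (20 of 22 higher, median 0.79, 0.70 at the floor, adjusted p = 3.54e-06) and regulatory genes (17 of 18 higher, median 0.53, 0.61 at the floor, adjusted p = 0.00143). Type 1 and cytotoxic genes (19 of 24 higher, adjusted p = 0.00132), chemokines (10 of 14, 0.000579), tissue residency (13 of 15, 0.000623), NF-kB (18 of 20, 0.00178), checkpoint (12 of 14, 0.0074), follicular helper (9 of 11, 0.00751), NK (13 of 15, 0.00883), cytokine (15 of 26, 0.035) and cholangiocyte lists (2 of 2, 0.000617) rose too. In wild type alone, of these rising lists only type 17 was called. Type 1 genes (9 of 24 higher, median -0.23 in wild type and 1.31 in knockout) and cytokines (-0.08 and 0.81) had medians of opposite sign. Tissue residency had 0.21 and 0.99 and TCR activation 0.27 and 1.33. None of these genotype differences was called with an estimated correlation. Mitochondrial shares were 51.1% and 52.7% in knockout control and 40.8% to 43.9% in other CD4+ libraries. The naive list fell (14 of 17 lower, median -0.74, -0.78 at the floor, adjusted p = 0.000175), as did ribosomal protein genes (81 of 83 lower, 2.15e-16), oxidative phosphorylation (37 of 54, 0.0125) and proliferation (24 of 32, 0.0407). Hepatocyte transcripts fell (16 of 18 lower, median -1.81, -2.18 at the floor, adjusted p = 2.46e-10), with Alb 4.85-fold lower. Endothelial (13 of 16 lower, 4.32e-05), stellate (7 of 9, 0.000617), macrophage (14 of 18, 0.0116) and B cell lists (10 of 15, 0.0219) fell too. Leaving out knockout control replicate 1 or 2, knockout MCD replicate 2, wild-type control replicate 2 or 3 or wild-type MCD replicate 3 gave 0 genes, and leaving out γδ MCD replicate 2 or 4 gave 23 or 24. DESeq2 called 196 genes and limma-voom 8. Without knockout MCD replicate 1 the type 1 call (adjusted p = 0.0532) was lost, and without knockout control replicate 1 the follicular helper call (0.0861). The checkpoint call was lost without knockout control replicate 1 or wild-type MCD replicate 3 (0.0605 to 0.0794), and the NK call without MCD replicate 1 of either genotype (0.0714 to 0.226). The oxidative phosphorylation, macrophage, cytokine, B cell and proliferation calls were each lost in 3 to 6 of the 12 fits without 1 library, at up to 0.0794, 0.209, 0.213, 0.232 and 0.17.

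The diet comparisons of the genotypes share no library. At an unadjusted p under 0.05, 44 genes were higher on the MCD diet in both genotypes (chance 5.84) and 21 lower in both (chance 4.32). In opposite directions, 2 genes were higher in wild type and lower in knockout (chance 3.42) and 15 the reverse (chance 7.37). These counts do not test a shared response. Over 6852 genes with a mean of at least 10 CPM, the log2 fold changes of the genotypes had a Pearson's r of 0.113 (Spearman 0.0769), across genes, which are not independent replicates.

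The genotype comparison on the control diet asked how CD4+ T cells differed in mice without γδ T cells when no steatohepatitis diet was given. Fgl2, for a secreted regulator of T cells (chromosome 5, 21372642 to 21378374), was 8.43-fold lower in knockout, at 14.6 ± 3.90 CPM against 123 ± 27.7 CPM in wild type (SD, n = 2; adjusted p = 0.0417). The collagen-binding integrin gene Itga1 (chromosome 13, 114953096 to 115101964) was 10.2-fold lower, at 9.90 ± 5.79 CPM against 100.7 ± 40.7 CPM (adjusted p = 0.0458). The γ-chain constant gene Tcrg-C4 (chromosome 13, 19344558 to 19352756), named after its values were seen, read 3.03 and 5.85 CPM in knockout and 79.6 and 103.2 CPM in wild type (log2 fold change -4.33, SE 0.53, adjusted p = 0.0117). The mitochondrial ribosomal RNA mt-Rnr2 was 1.6-fold higher (log2 fold change 0.68, SE 0.08, adjusted p = 0.0117). In each of these 4 genes the libraries of the genotypes did not overlap.

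Groups of effector and innate-like T cell genes were lower in knockout control CD4+ T cells at the preset correlation, and with an estimated correlation none of the 12 called lists held (adjusted p = 0.253 to 0.284). The tissue residency list fell (13 of 15 lower, median -1.26, -1.27 at the floor, adjusted p = 0.000165), with Cxcr6 3.83-fold, Bhlhe40 3.31-fold and Rgs1 2.04-fold lower. Type 1 and cytotoxic genes (20 of 24 lower, median -1.15, -1.16 at the floor, adjusted p = 0.000326; Il12rb2 6.76-fold), NKT genes (10 of 12 lower, median -1.40, -1.39 at the floor, adjusted p = 0.000326; Klrb1c 10.6-fold and Klrk1 6.27-fold) and NK genes (10 of 15 lower, median -1.06, -1.18 at the floor, adjusted p = 0.0123; Klrc1 9.60-fold) fell. Type 2 genes (7 of 9 lower, median -1.45, -2.46 at the floor, adjusted p = 0.00408; Il4 49.3-fold), TCR activation (18 of 22 lower, median -0.70, -0.72 at the floor, adjusted p = 0.00709; Egr3 4.76-fold and Il2ra 2.78-fold) and chemokines (12 of 14 lower, median -0.58, -0.92 at the floor, adjusted p = 0.0465) also fell. The naive and central memory list was higher in all 17 members (median 0.82, 0.83 at the floor, adjusted p = 1.02e-05), with Tcf7 at 970 ± 163 CPM against 449 ± 49.7 CPM (SD, n = 2) and Il7r 1.64-fold higher. Ribosomal protein genes (79 of 83 higher, median 0.77, adjusted p = 3.71e-15; Rpl4 1.83-fold) and mitochondrial mRNA (11 of 13 higher, median 0.59, adjusted p = 0.00242; mt-Co1 1.5-fold), both lists added after the data were seen, rose. Mitochondrial genes took 51.1% and 52.7% of the counts in these knockout libraries. Endothelial (13 of 16 lower, median -0.94, -1.06 at the floor, adjusted p = 0.00774) and erythroid transcripts (3 of 3 lower, median -1.70, -2.04 at the floor, adjusted p = 0.0444) fell. The type 17, regulatory and checkpoint lists were not called (adjusted p = 0.547 to 0.875).

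On the control diet 4 of 16218 genes passed edgeR's test between genotypes, 1 higher and 3 lower in knockout, and 653 had an unadjusted p under 0.05, 200 higher and 453 lower, fewer than the 811 given by chance. Without 1 library, the calls of Tcrg-C4 and mt-Rnr2 were kept in 9, that of Fgl2 in 6 and that of Itga1 in 2 of the 12 fits (adjusted p up to 0.471). The log2 fold change of Itga1, -3.33 over all libraries, was -4.09 without knockout control replicate 2. Under other settings, 9 of 15 kept the Itga1 call (adjusted p up to 0.326), 10 of 15 that of Fgl2, and 12 and 10 of 14 those of Tcrg-C4 and mt-Rnr2. DESeq2 called 122 genes and limma-voom 6. Leaving out knockout control replicate 1 or wild-type control replicate 3 gave 0 genes, knockout control replicate 2 gave 1, and wild-type control replicate 2 or γδ control replicate 6 or 7 gave 2. Below the threshold, Itgax was at least 43.7-fold and Cd93 122-fold lower (adjusted p = 0.0788 and 0.093), and Pik3ap1, with 2 counts in knockout, had a ratio of 106 (95% counting interval 29.0 to 881). The γ-chain gene Tcrg-C1 was 12.9-fold lower (adjusted p = 0.773), mt-Rnr1 was 1.63-fold higher (0.0788), and Ssh2 and Add3 were 2.10-fold and 2.5-fold higher (0.235). Without knockout control replicate 1 or wild-type control replicate 3 the type 1 (adjusted p = 0.0529 to 0.0607), type 2 (0.0541 to 0.0551), NK (0.143 to 0.231) and mitochondrial mRNA calls (0.0551 to 0.067) were lost. The NKT call was lost without knockout control replicate 1 (0.0551), and TCR activation without that library or wild-type control replicate 2 (0.219 to 0.227). The endothelial call was lost without knockout control replicate 2 or wild-type control replicate 3 (0.0626 to 0.198). The chemokine and erythroid calls were lost in 6 and 5 of the 12 fits without 1 library, at up to 0.148 and 0.231.

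**Figure D3:**
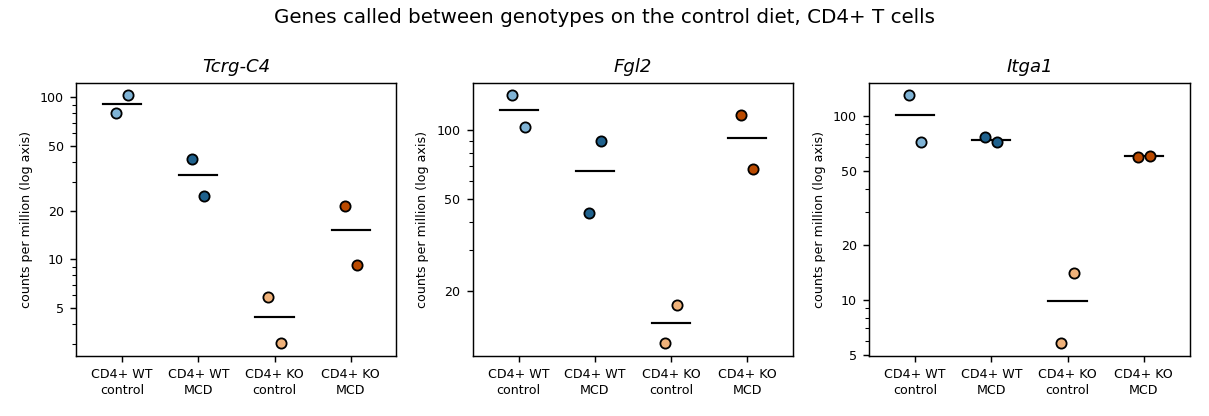
CPM on a log axis of 3 genes called between genotypes on the control diet in CD4+ T cells, with 1 point per library and a line at the mean of 2. Fgl2 read 11.8 and 17.3 CPM in knockout control libraries and a mean of 123 CPM in wild-type control libraries.

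The genotype comparison on the MCD diet asked how CD4+ T cells differed with and without γδ T cells during steatohepatitis. Rgs1 read 486 ± 0.361 CPM (SD, n = 2) in knockout and 221 ± 50.1 CPM (SD, n = 2) in wild type, and Maf read 265 ± 6.53 CPM against 121 ± 28.8 CPM. Ccl5 read 147 ± 26.4 CPM against 68.0 ± 1.01 CPM, and osteopontin (Spp1) read 34.6 ± 0.156 CPM against 0.869 ± 0.534 CPM. The phosphatase gene Mtmr9 read 126 ± 28.5 CPM against 11.9 ± 2.81 CPM (SD, n = 2). Each gene had an adjusted p of 1, and the lack of overlap is again common by chance.

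On the MCD diet 0 of 16218 genes passed edgeR's test between genotypes, with 337 at an unadjusted p under 0.05, 184 higher and 153 lower in knockout, fewer than the 811 given by chance. DESeq2 called 39 genes and limma-voom 0. Besides Mtmr9 and Rgs1, small p-values among higher genes with a mean of at least 5 CPM in the higher group were those of Gnai3 (2.69-fold) and Fn1 (10.1-fold). Among lower genes under the same limit they were those of Papss2 (15.7-fold), Adgra3 (at least 52.4-fold), Ssh2 (1.55-fold), Trim2 (71.7-fold) and Kcnq1ot1 (2.03-fold). The list for cholangiocytes was the only 1 of 49 lists called (2 of 2 measured members higher, median 3.32, 3.51 at the floor, adjusted p = 0.00829), and it was not called with an estimated correlation (0.347) or without knockout MCD replicate 2 (0.0949). The type 17, type 1 and cytotoxic, regulatory, naive, TCR activation and checkpoint lists were not called (adjusted p = 0.176 to 0.75). Averaged over both diets, Tcrg-C4 was the only gene called between genotypes (log2 fold change -2.72, SE 0.35, adjusted p = 0.0388), with 717 genes at an unadjusted p under 0.05 against 811 given by chance. The Tcrg-C4 call was kept in 4 of the 12 fits without 1 library. Tcrg-C4 read 3.03 to 21.3 CPM in the 4 knockout and 24.6 to 103.2 CPM in the 4 wild-type libraries. Itgax was 15.6-fold lower, Itga1 2.5-fold lower and mt-Rnr2 1.31-fold higher without passing (adjusted p = 0.105 to 0.345).

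In that average over diets, the NKT list fell in knockout (11 of 12 lower, median -1.08, -1.09 at the floor, adjusted p = 0.000404), with Klrb1c 3.21-fold lower. None of the 9 lists called in this average held with an estimated correlation (adjusted p = 0.403 to 0.492). Type 2 genes (8 of 9 lower, 0.032), tissue residency (9 of 15 lower, 0.0301; Zfp683 3.41-fold) and erythroid transcripts (3 of 3 lower, 0.0498) fell. Naive genes (15 of 17 higher, 0.00767), ribosomal protein genes (78 of 83 higher, 5.93e-06), mitochondrial mRNA (10 of 13 higher, 0.00767), B cell (13 of 15 higher, 0.00682) and cholangiocyte transcripts (2 of 2 higher, 0.0159) rose. The type 17, type 1 and cytotoxic, regulatory, TCR activation and checkpoint lists were not called (0.0881 to 0.855). The NKT and ribosomal calls were kept in all 12 fits without 1 library, and the other 7 were each lost in 2 to 8 of them. Leaving out 1 library gave 0 to 4 genes in this average, 4 without γδ MCD replicate 2 or 4, 2 without knockout MCD replicate 1 or wild-type MCD replicate 3, and 0 without knockout control replicate 1, knockout MCD replicate 2, either wild-type control replicate, wild-type MCD replicate 1 or either γδ control replicate. DESeq2 called 76 genes and limma-voom 0.

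The test of genotype by diet asked whether the diet acted differently on CD4+ T cells of the 2 genotypes. Rgs1 had a log2 difference of diet effects (knockout minus wild type) of 2.16 (SE 0.40), Fgl2 of 3.54 (SE 0.59), Slamf7 of 3.35 (SE 0.60) and Cd93 of 7.29 (SE 1.35), each with adjusted p = 0.299. Itga1 differed by 3.03 (SE 0.65, adjusted p = 0.554), Maf by 2.08 (SE 0.46, 0.63) and Ccl3 by 8.06 (SE 2.28, 1). On the other side, Ssh2 differed by -1.70 (SE 0.30) and mt-Rnr2 by -0.64 (SE 0.12), both at 0.299. Lars2 (-2), Thy1 (-2.10), Add3 (-1.51) and the naive-cell regulator Tcf7 (-1.19) followed (adjusted p = 0.673 to 1). So 0 of 16218 genes passed edgeR's test, with 703 at an unadjusted p under 0.05, 463 higher and 240 lower, fewer than the 811 given by chance. DESeq2 called 71 genes and limma-voom 1, and leaving out γδ MCD replicate 2 or 4 gave 1. The camera test called 11 of 49 lists, type 1 and cytotoxic genes higher (20 of 24, median 1.48, adjusted p = 0.00078) and naive genes lower (17 of 17, median -0.75, adjusted p = 0.00078) among them. The type 17, regulatory and checkpoint lists were not called (0.154 to 0.374), and no list was called with an estimated correlation (adjusted p = 0.205 to 0.343 in the 11). The type 1, naive and ribosomal calls were kept in all 12 fits without 1 library. The residency call was lost without knockout MCD replicate 1 (0.104), the chemokine call without wild-type MCD replicate 1 (0.0906), and the TCR activation call without knockout control replicate 1 or wild-type control replicate 2 (0.0914 to 0.098).

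The comparison of γδ with CD4+ T cells in wild-type mice, averaged over both diets, asked what set γδ T cells apart. Trdc was 388-fold higher in γδ T cells, at 635 ± 80.2 CPM against 1.64 ± 1.30 CPM (SD, n = 4; adjusted p = 3.39e-05), and Cd4 was 404-fold lower, at 1.87 ± 1.62 CPM against 756 ± 102 CPM (adjusted p = 6.02e-08). The interleukin-23 receptor gene Il23r, of cells that make interleukin-17, was 162-fold higher, at 44.5 ± 22.0 CPM against 0.275 ± 0.403 CPM (adjusted p = 0.00428). The regulatory T cell factor Foxp3 was 45.7-fold lower, at 1.06 ± 2.07 CPM against 48.5 ± 11.2 CPM (adjusted p = 0.000785). In each of these genes the 4 γδ libraries lay on the same side of the 4 CD4+ libraries. Foxp3 read 0 to 0.08 CPM in 3 γδ libraries and 4.17 CPM in MCD replicate 4, and its log2 fold change went from -6.65 to -8.49 without that library. That of Trdc went from 8.51 to 9.65 without wild-type CD4+ MCD replicate 1, and that of Il23r from 6.93 to 7.88 without wild-type CD4+ control replicate 3.

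Among the called genes with the largest changes, Cd163l1 (1490-fold), Tns4 (1200-fold), Ptafr (1080-fold), Tnfrsf21 (633-fold), Fn1 (384-fold) and Ncr1 (at least 280-fold) were higher in γδ T cells. Sox13, with 1 count in CD4+ T cells, had a ratio of 2740 (95% counting interval 491 to 108000), and Thbd, with 3 counts, had a ratio of 1410 (483 to 6860). U2af1l4 (182-fold), Sgo1 (159-fold), Als2cl (67.1-fold), Lgals4 (at least 48.8-fold) and Sele (at least 39.4-fold) were lower, and Il1rl1, with 2 counts in γδ T cells, had a ratio of 359 (99.0 to 2970). Fitted log2 fold changes moved by over 1.5 times without 1 library in these genes. Without γδ MCD replicate 4, Tns4 went from 9.18 to 8.11, Ncr1 from 8.26 to 7.5 and Sox13 from 8.05 to 7.16. Without γδ control replicate 7, Ptafr went from 8.73 to 7.61, Thbd from 8.43 to 7.47, Tnfrsf21 from 8.06 to 7.2, Fn1 from 7.97 to 7.3 and U2af1l4 from -6.75 to -7.45. Without γδ MCD replicate 2, Thbd was 6.08, Tnfrsf21 6.33 and U2af1l4 -7.36. Fn1 was 9.04 without wild-type CD4+ MCD replicate 1, and Il1rl1 went from -6.2 to -5 without wild-type CD4+ control replicate 3. Sgo1 went from -6.4 to -7.2 without γδ control replicate 6 and to -5.68 without wild-type CD4+ control replicate 2. Its call was lost there and without either wild-type CD4+ MCD library or γδ control replicate 7 (adjusted p = 0.0537 to 0.0744). The Thbd call was lost without either wild-type CD4+ MCD library (0.0527 and 0.0529) and the Lgals4 call without γδ control replicate 7 (0.0557). In total 966 of 16218 genes passed edgeR's test, 555 higher and 411 lower in γδ T cells, and 4223 had an unadjusted p under 0.05, against 811 given by chance. DESeq2 called 3069 genes and limma-voom 1625. Scaling by library size alone shifted the median of all genes by a further -0.61 log2 from -0.23 and turned the split from 57.5% higher of 966 to 16.7% higher of 1981. Leaving out 1 wild-type CD4+ library gave 311 to 350 genes, γδ control replicate 6 gave 549 and replicate 7 gave 428, γδ MCD replicate 2 gave 1585 and replicate 4 gave 2548.

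The γδ lineage list rose in 13 of 14 members (11 called, median 4.92, 5.35 with genes at 0 set at the floor, adjusted p = 2.65e-14), with Tcrg-C1 14.8-fold higher. Of the 26 lists called between these cells, 19 held with an estimated correlation, and those for type 2, tissue residency, NKT, TGF beta, glycolysis, CD8 T cells and ribosomal proteins did not (adjusted p = 0.0787 to 0.303). The type 17 list rose (15 of 16 higher, 9 called higher and 1 lower, median 2.84, 2.94 at the floor, adjusted p = 5.85e-09), with Il18r1 4.20-fold and Tmem176a 13.2-fold higher and Il21 at least 15.1-fold lower. Adjusted over the list alone, 12 of its members were higher and 1 lower. Type 1 and cytotoxic genes rose (21 of 24 higher, 5 called, median 1.16, 1.27 at the floor, adjusted p = 1.32e-05), with Ccl5 5.13-fold, Gzma 38.2-fold and Gzmb 7.56-fold higher. Chemokines (14 of 14 higher, 5 called, adjusted p = 3.34e-08), tissue residency (13 of 15 higher, 5 called, 0.000338; Itga1 3.34-fold) and innate receptors (19 of 21 higher, 9 called, median 3.99, 4.15 at the floor, 5.15e-12; Tlr7 17.7-fold) rose. Trafficking receptors rose relative to all genes (18 of 25 higher, 9 called, adjusted p = 0.000545), with Cx3cr1 311-fold and Ccr2 4.96-fold higher, though their median of 0.62 (0.69 at the floor) became -0.03 under library-size scaling. The CD4 lineage list fell (9 of 10 lower, 3 called, median -1.54, -1.36 at the floor, adjusted p = 0.00195; Trac 8.06-fold), as did naive genes (15 of 17 lower, 7 called, median -1.18, -1.13 at the floor, 0.00027; Satb1 2.29-fold and St8sia6 22.2-fold) and follicular helper genes (9 of 11 lower, 4 called, median -2.85, -1.57 at the floor, 0.000545; Slamf6 7.21-fold). The log2 fold change of Gzma, 5.17, was 6.22 or 6.84 without wild-type CD4+ control or MCD replicate 3 and 3.82 without γδ MCD replicate 4. That of Cx3cr1, 7.87, was 8.61 or 8.49 without wild-type CD4+ control replicate 2 or MCD replicate 3. The Gzma call was lost without wild-type CD4+ control replicate 2 (adjusted p = 0.0614), the Tmem176a call without wild-type CD4+ MCD replicate 3 (0.0502), and the Gzmb and Itga1 calls without wild-type CD4+ control replicate 3 (0.0704 and 0.0557) or wild-type CD4+ MCD replicate 3 (0.074 and 0.0512). Proliferation (27 of 32 lower, 3 called, median -1.31, -0.71 at the floor, 0.00052) and type 2 genes (6 of 9 lower, 3 called, median -2, -0.67 at the floor, 0.0129) fell.

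Metabolic and stress groups differed too, but RNA of other cells in the γδ libraries was not separated. The oxidative stress (NRF2) list rose (22 of 23 higher, 7 called, median 1.43, 1.49 at the floor, adjusted p = 2.17e-09), with Fth1 3.49-fold, Sod2 3.71-fold and Cat 2.54-fold higher. Fatty acid uptake and storage rose (20 of 23 higher, 3 called, median 1.13, 1.17 at the floor, adjusted p = 0.000667), with Lpl 28.8-fold, Apoe 13.9-fold and Cd36 121-fold higher. The log2 fold change of Lpl, 4.67, was 5.38 or 5.41 without wild-type CD4+ control or MCD replicate 3 and 3.9 without γδ control replicate 7. That of Apoe, 3.72, was 4.36 without wild-type CD4+ MCD replicate 3. That of Cd36, 6.25, was 7.38 or 7.1 without wild-type CD4+ control replicate 2 or MCD replicate 3 and 5.22 without γδ control replicate 7. The Cd36 call was lost without γδ control replicate 7 or any wild-type CD4+ library but control replicate 2 (adjusted p = 0.0586 to 0.103), and the Apoe call without any wild-type CD4+ library but MCD replicate 3 (0.0724 to 0.0924). The unfolded protein response list rose relative to all genes (17 of 22 higher, 4 called, adjusted p = 0.000545; Hsp90b1 2.45-fold and Pdia3 2.46-fold), with a median of 0.46 (0.47 at the floor) that became -0.23 under library-size scaling. Glycolysis (11 of 16 higher, 1 called, 0.0455) and ribosomal protein genes (64 of 83 higher, 3 called, 1.32e-05) also rose, with medians of 0.54 and 0.34 (0.54 and 0.36 at the floor) that became -0.12 and -0.33 under that scaling, where neither was called (0.235 and 0.328). TGF beta and fibrosis mediators (11 of 17 higher, 2 called, 0.0419) and NKT genes (9 of 12 higher, 4 called higher and 2 lower, 0.0419) rose. These, glycolysis and ribosomal proteins did not hold with an estimated correlation (0.12, 0.257, 0.238 and 0.303). Mitochondrial mRNA rose in 13 of 13 members (7 called, median 1.56, 1.68 at the floor, adjusted p = 2.5e-09), with mt-Nd2 4.81-fold higher. Not called were T cell core (1 called higher and 4 lower, 0.315; Cd3e 1.86-fold higher), regulatory (2 called higher and 6 lower, 0.315; Ctla4 27.9-fold lower, its log2 fold change going from -5.46 to -7.77 without γδ control replicate 6), TCR activation (3 called higher and 1 lower, 0.106; Cd44 3.02-fold and Myc 3.71-fold higher, the Myc call being lost without any 1 wild-type CD4+ library or either γδ control library, at 0.0533 to 0.114), checkpoint (1 called higher and 2 lower, 0.122) and guanylate binding proteins (2 called higher and 1 lower, 0.169).

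Markers of other cells were part of what set the γδ libraries apart. Lyz2, abundant in myeloid cells, read 1165 ± 413 CPM in γδ and 10.9 ± 8.31 CPM in CD4+ T cells (SD, n = 4; adjusted p = 2.15e-05), and the MHC class II chaperone Cd74 read 2268 ± 690 CPM against 53.8 ± 6.03 CPM (adjusted p = 2.64e-07). The neutrophil and monocyte list rose (14 of 15 higher, 7 called, median 4.34, 5.58 at the floor, adjusted p = 5.15e-12; Itgam 51.2-fold), as did macrophage and Kupffer genes (15 of 18 higher, 6 called, median 3.75, 3.11 at the floor, 2.5e-09; Csf1r 41.0-fold) and dendritic and MHC class II genes (14 of 16 higher, 6 called, median 2.32, 3.96 at the floor, 2.52e-09; H2-Ab1 37.9-fold). NK genes (14 of 15 higher, 6 called, median 2.73, 3.16 at the floor, 2.95e-10; Fcer1g 64.4-fold and Tyrobp 25.2-fold), endothelial genes (15 of 16 higher, 2 called, median 2.71, 4.27 at the floor, 2.79e-08) and the CD8 pair (2 of 2 higher, 1 called, 0.0129; Cd8a 23.9-fold) rose. Without wild-type CD4+ control replicate 2 the log2 fold change of Itgam went from 5.64 to 6.83 and that of Fcer1g from 6.02 to 6.66. Without γδ MCD replicate 2 the type 2 call was lost (0.0919), and without γδ MCD replicate 4 the CD8 call (0.0542). The NKT, TGF beta and glycolysis calls were lost in 5, 3 and 6 of the 12 fits without 1 library.

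**Figure D4:**
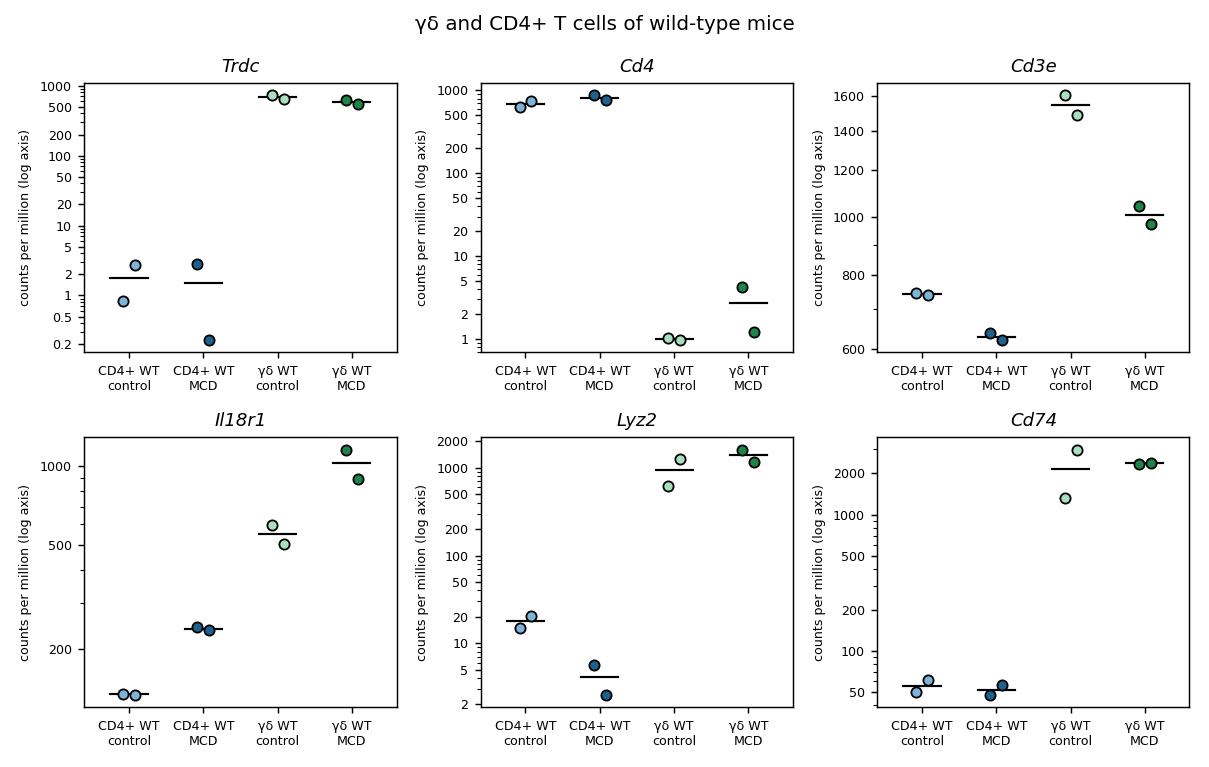
CPM on a log axis in wild-type CD4+ and γδ T cells by diet, with 1 point per library and a line at the mean of 2. Trdc read 538 to 733 CPM in the 4 γδ libraries and 0.23 to 2.8 CPM in the 4 CD4+ libraries, and Lyz2 read 616 to 1616 CPM and 2.59 to 20.6 CPM.

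The test of cell type by diet asked whether the diet acted differently on γδ and CD4+ T cells of wild-type mice. Kmt5a had a log2 difference of diet effects (γδ minus CD4+) of 2.58 (SE 0.48), Spsb1 of 8.37 (SE 1.45) and Xylt1 of 3.36 (SE 0.66), each with adjusted p = 0.292. Trmt61a differed by -8.27 (SE 1.27) and Cep97 by -5.47 (SE 0.81), both with adjusted p = 0.132. Chst2 differed by -7.16 (SE 1.18, 0.182) and Kif11 by -6.44 (SE 1.26, 0.292). The neutrophil and monocyte list was higher (13 of 15, median 1.42, adjusted p = 0.00148; Csf3r 9.42, SE 2.61), as was the hepatocyte list (13 of 18, median 2.10, adjusted p = 0.0132). The sinusoidal endothelium list was lower (15 of 16, median -3.47, adjusted p = 0.000171; Oit3 -5.98, SE 2.51). None of these 3 lists was called with an estimated correlation (0.278 to 0.291), and the type 17, type 1, regulatory, naive, TCR activation and checkpoint lists were not called (0.467 to 0.87). No gene passed edgeR's test (0 of 16218), with 1714 at an unadjusted p under 0.05, 563 higher and 1151 lower, against 811 given by chance. DESeq2 called 645 genes and limma-voom 0, and leaving out γδ MCD replicate 2 gave 37 and γδ MCD replicate 4 gave 455. The hepatocyte call was lost without wild-type CD4+ MCD replicate 3, γδ control replicate 6 or γδ MCD replicate 2 (0.0762 to 0.235), and the neutrophil call without γδ MCD replicate 4 (0.0732).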

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

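The tests of γδ T cell RNA, NK cell RNA, Kupffer cell RNA, carried-over cells and the distance between naive and effector medians, and the counts over other splits of the libraries, were chosen only after the results were seen.

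Differences between groups in the effect of the diet appeared in gene lists, by camera tests of the interaction. Between genotypes, the diet effect in CD4+ T cells was higher in knockout for type 1 and cytotoxic genes (median log2 difference 1.48, adjusted p = 0.00078), tissue residency (0.89, 0.00146), TCR activation (1.14, 0.00465), chemokines (1.70, 0.00574), follicular helper genes (0.27, 0.0186), cytokines (0.59, 0.0251) and type 2 genes (2.5, 0.0258). It was also higher for sinusoidal endothelium (2.03, 0.00896) and the 2 cholangiocyte genes (3.40, 0.0273). It was lower in knockout for naive and central memory genes (-0.75, 0.00078) and ribosomal proteins (-0.89, 8.22e-11). With an estimated correlation the adjusted p of these 11 lists was 0.205 to 0.343, and by fry 0.102 to 0.189. Among the 12 fits without 1 library, the follicular helper call was lost without knockout control 1, knockout MCD 1 or wild-type MCD 3 (0.0653 to 0.267). The cytokine call was lost without knockout control 1, knockout MCD 1, wild-type control 2 or wild-type MCD 1 (0.121 to 0.239), and the type 2 call without knockout control 1, knockout MCD 1, wild-type control 3 or wild-type MCD 1 (0.0901 to 0.208). The endothelial call was lost without knockout control 2 or knockout MCD 1 (0.0653 to 0.0756), and the cholangiocyte call without knockout control 1, either knockout MCD library, wild-type control 2 or wild-type MCD 1 (0.0625 to 0.239). Residency, chemokine and TCR activation calls were lost in 1, 1 and 2 of these fits. Between γδ and CD4+ T cells of wild-type mice, the diet effect was higher in γδ T cells for neutrophil and monocyte (1.42, 0.00148) and hepatocyte transcripts (2.10, 0.0132) and lower for sinusoidal endothelium (-3.47, 0.000171). These 3 had an adjusted p of 0.278 to 0.291 with an estimated correlation and 0.0377 to 0.071 by fry.

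In CD4+ T cells on the control diet, effector and NK-receptor genes were lower and naive genes higher in knockout than in wild type, by camera at its preset correlation, and the interaction rests on the same control libraries. None of the 12 lists called there held with an estimated correlation (adjusted p = 0.253 to 0.284). γδ T cell RNA in the wild-type libraries was argued against, since the share implied by Tcrg-C4, 12.7%, would bring 87.6 CPM of Trdc where 1.76 CPM was observed, a ratio of 0.0201. NK cell RNA stays open. Tyrobp, Fcer1g, Gzma and Ncr1 (median log2 fold change 0.64) had group means of 0 to 7.07 CPM. The NK list went the other way (median -1.06). Leaving out mitochondrial and ribosomal RNA genes tested little, since it moved the median of all genes by -0.019 log2 and that of the naive list by -0.011 (adjusted p = 1.08e-05 without them). Mitochondrial ribosomal RNA lowering all other genes alike would by itself not change the median log2 CPM of naive genes minus that of effector and NK genes. That distance was 5.04 and 4.91 in knockout control and 2.45 and 2.26 in wild-type control libraries, a difference of 2.62. Such a lowering alone would not give this difference. The lists are those of the pattern itself, however, so the distance restates it and adds no separate evidence. Whether the larger mitochondrial share went with the pattern in another way cannot be told apart with these tables. The genotype itself and a different mix of CD4+ T cell subsets stay open, untested.

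Fewer genes were detected in the γδ libraries of the MCD diet, and proliferation, sterol synthesis and endothelial lists were lower there by camera at its preset correlation. None of the 10 lists called between these diets held with an estimated correlation (adjusted p = 0.082 to 0.455), and the sterol call was lost without control replicate 6 or MCD replicate 4 (0.0536 to 0.0675). After thinning to equal non-mitochondrial totals these libraries had 8968 and 9988 genes with at least 10 reads, against 11527 in the lowest of the other 10, which argues against sequencing depth. For random loss of transcripts, the list medians were set among those of 10000 lists matched on control expression. They lay at percentiles 0.15 (proliferation), 0.16 (sterol synthesis) and 0 (sinusoidal endothelium). The oxidative stress list lay at percentile 100. These lists had been called in the same comparison, and the matched lists were drawn gene by gene, without correlation between members. So the percentiles do not decide on random loss of transcripts, which stays open. The diet, a lower amount of intact RNA and a different mix of sorted cells stay open too, untested.

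Myeloid and MHC class II transcripts were present in all 4 γδ libraries, with Lyz2 at 616 to 1616 CPM. Kupffer cell RNA of a single profile was argued against, because Kupffer markers over Lyz2 and Csf1r fell on the MCD diet to a ratio of 0.188 of control, from 0.139 and 0.162 to 0.00976 and 0.0469 per library. Other cells carried through the sort cannot be told apart from expression by the γδ T cells, since the T cell core list had a median log2 fold change of -0.37 against CD4+ T cells, with members going both ways. No biological explanation was tested.

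The counts over splits came from fits of 8 libraries with the split as the only term, not from the fit of 12. Over all 35 splits of the 8 wild-type libraries into groups of 4, the real split of γδ and CD4+ T cells called 390 genes. The highest of the others called 0 (1 split as large). Every other split put both cell types on both sides, so their low counts were set in large part by the design. These counts therefore do not decide on chance. Over the 35 splits of the 8 CD4+ libraries, the diet split called 6 genes and the highest other split 1 (1 split as large). Every other split put both diets on both sides, and 1 of 35 is the smallest share that these splits can give. So these counts do not decide on chance either. The genotype split called 1 gene and the highest other split, which was the diet split, 6, so chance was not excluded (2 splits as large). The structure of the samples behind that higher count is the diet, a group of the study, so it does not tell how often chance alone gives 1 gene.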

How the results depend on the processing

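The settings without mitochondrial and ribosomal RNA genes, with CD4+ libraries only and with voom quality weights were chosen after seeing the data. Counts of called genes are given in the order of the comparison named, and where a count moved the cause was not tested unless the setting tests fewer genes or samples.

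The reported counts were 0 for diet in γδ, 0 in wild-type CD4+ and 6 in knockout CD4+ T cells, 0 for genotype on the MCD and 4 on the control diet, 0 for genotype by diet, 966 for γδ against CD4+ T cells, 0 for cell type by diet, 6 for the diet average and 1 for the genotype average. DESeq2 gave 2105, 40, 266, 39, 122, 71, 3069, 645, 196 and 76 in that order. Testing with no filter on low counts gave 555, 19, 105, 11, 52, 44, 1588, 113, 106 and 37.

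With limma-voom the counts were 63 for diet in γδ and 19 in knockout CD4+ T cells, 1 for genotype by diet, 1625 for γδ against CD4+ and 0 for the genotype average. Voom with quality weights gave 3 for diet in γδ, 38 in knockout CD4+, 19 for genotype on the control diet, 1 for genotype by diet and 69 for the diet average. A robust spread gave 5 for diet in γδ T cells. Library-size scaling gave 3 for diet in γδ, 10 in knockout CD4+ and 1981 for γδ against CD4+ T cells. It moved the median of all genes by -0.20 log2 for diet in γδ, 0.29 for diet in knockout, -0.34 for genotype on the control diet, 0.29 for genotype by diet, -0.17 for cell type by diet, 0.14 for the diet average and -0.20 for the genotype average. RLE scaling kept every count within 1.5 times.

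With log2 FPKM and a pseudocount of 1 the counts were 148 for diet in γδ, 15 in knockout CD4+, 5 and 2 for genotype on the MCD and control diets, 11 for the diet average and 0 for the genotype average. With a pseudocount of 0.1 they were 210 for diet in γδ, 3 for cell type by diet, 1 for the diet average and 0 for the genotype average. A mean of at least 50 reads gave 3 for diet in knockout CD4+, and thinning to equal totals gave 3 for diet in γδ T cells. Without receptor segments, genotype on the control diet gave 1 and the genotype average 0. The setting without mitochondrial and ribosomal RNA genes kept every count within 1.5 times.

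Fitting only the groups compared gave 9 for diet in γδ, 28 in knockout CD4+, 1 and 11 for genotype on the MCD and control diets, 1 for genotype by diet, 517 for γδ against CD4+, 84 for the diet average and 3 for the genotype average. CD4+ libraries only gave 113 for diet in knockout, 1 and 8 for genotype on the MCD and control diets, 1 for genotype by diet, 84 for the diet average and 3 for the genotype average. In the CD4+ comparisons both settings leave out the γδ libraries, whose spread otherwise enters the shared estimate.

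Leaving out each library in turn, with the lone sample assumed to vary like the other groups, gave 0 to 1342 for diet in γδ, 0 to 0 in wild-type and 0 to 42 in knockout CD4+ T cells. It gave 0 to 0 for genotype on the MCD and 0 to 6 on the control diet, 0 to 1 for genotype by diet, 311 to 2548 for γδ against CD4+, 0 to 455 for cell type by diet, 0 to 24 for the diet average and 0 to 4 for the genotype average. Camera called 118 lists in total, and the total was 83 to 122 without 1 library, 21 with an estimated correlation and 78 by fry. Of the 118 calls, 83 to 109 were kept without 1 library, 21 with an estimated correlation and 63 by fry. RLE scaling kept 117 and library-size scaling 104, and with CD4+ libraries only 70 calls were kept and 9 lost. The 14 calls lost under library-size scaling were type 17 for diet in γδ (adjusted p = 0.0538), type 2 and oxidative phosphorylation for diet in knockout (0.0654 and 0.109), and chemokines and erythroid for genotype on the control diet (0.112 and 0.0513). The others were cholangiocyte for genotype by diet (0.0561), TGF beta, glycolysis and ribosomal proteins for γδ against CD4+ (0.0513, 0.235 and 0.328), cytokines and proliferation for the diet average (0.0506 and 0.0579), and type 2, naive and erythroid for the genotype average (0.0505, 0.0596 and 0.0596). With CD4+ libraries only the losses were type 2 for diet in knockout (0.101), erythroid for genotype on the control diet (0.0599), type 2 and cholangiocyte for genotype by diet (0.0632 and 0.0509), cytokines and B cells for the diet average (0.0566 and 0.0524), and type 2, residency and erythroid for the genotype average (0.0645, 0.0676 and 0.0674). RLE scaling lost the erythroid call of the genotype average (0.0522).

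A replicate block over the same-numbered knockout libraries gave 7 for diet in knockout CD4+ T cells, and the correlation of same-numbered deviations across genes was -0.00589, so the labels' numbers gave no sign of pairing. Other groups share fewer than 2 replicate numbers, so no pairing by number was used there, and a block over all 8 CD4+ libraries was not fitted. The label code of γδ MCD replicate 2 also carries the code of the wild-type MCD CD4+ replicate 1 library, so its replicate number, and whether it shares a source with that library, is not settled by the labels.

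Of 3147 values of the 215 named results under other settings, 2727 kept their direction and side of the threshold, 67 lost a call, 353 gained one and 0 changed sign. Of 2580 values without 1 library, 2337 kept both, 129 lost a call, 112 gained one and 2 changed sign. Those 2 were Il17a between diets in γδ T cells, at -0.25 log2 without MCD replicate 4 (range -0.25 to 4.41 without 1 library), and Csf3r between diets in wild-type CD4+ T cells, at 0 without control replicate 3, the single library of the 4 with reads (range -7.62 to 0). The cause was not tested for Il17a. Depth limits what can be said of genes near the floor of 3 counts.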

Other observations

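The test of genes near Trdc was chosen only after the result was seen.

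Receptor variable segments in the γδ libraries, given as raw counts, showed which chains were read. Trgv2 had 1211 to 1467 counts on the control diet and 766 to 1007 on the MCD diet, and Tcrg-V4 had 589 to 882 and 240 to 507. Tcrg-V6 had 43 to 127 and 15 to 235, Tcrg-V7 had 108 to 324 and 13 to 29, and Tcrg-V5 had 21 to 86 and 0 to 2. Of the δ segments, Trdv4 had 75 to 637 and 67 to 216, Trdv5 had 90 to 270 and 84 to 175, Trdv2-2 had 81 to 199 and 1 to 29, and Trdv1 had 30 to 165 and 2 to 3.

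In CD4+ T cells, some genes near Trdc (chromosome 14, 54142851 to 54148868) differed between genotypes. Within 10 Mb of Trdc, 5 of 183 genes (2.73%) had an unadjusted p under 0.01 in the genotype average, against 77 of 15227 elsewhere (0.506%; Fisher's exact test, 2-sided, p = 0.00292). The window was set after Mtmr9 had been noticed, so these counts describe the genes and do not test an explanation. Mtmr9 (start 63519651) read 63.6 to 146 CPM in knockout and 9.93 to 18.3 CPM in wild type, Ppp1r3e (54872669) read 0 to 0.875 and 4.16 to 20.3 CPM, and Atp8a2 (59638540) read 2.98 to 32.7 and 57.9 to 96.6 CPM. None passed the adjustment over all genes (adjusted p = 0.347 to 1). A candidate explanation, untested here, is a chromosome segment of another strain inherited with a targeted allele at Trdc, although the labels give C57BL/6 for the wild type and state neither the allele nor the background of the knockout.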
